A study of Mus musculus with 2 samples.

How the data were processed

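Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against histone H3 acetylated at lysine 9 (H3K9ac), a modification found at the start sites of active genes and at some active enhancers. The material was whole liver from mouse embryos at embryonic day 15.5, of a C57BL/6-derived strain (B6NCrl). Per the labels, replicate 1 was pooled from 78 embryos and replicate 2 from 62 embryos, both of mixed sex, and they are biological replicates; 1 technical replicate was named for replicate 1 and 2 were named for replicate 2. Both libraries belonged to 1 group, and there was no second condition, so no comparison between groups was made. The labels name an input control that was not used here.

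The authors deposited 4 lists of peaks on the mm10 assembly: 1 per replicate, 1 called on both replicates together (the pooled list) and 1 that keeps the peaks they counted as replicated (the replicated list). Each peak carries a signal value that the authors deposited with it, whose scale is not given in the sources used here. Each peak also carries a −log10 p and a −log10 q that the authors deposited. The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here. The authors' signal was used only to describe, rank or filter peaks within 1 list, never as a change between lists. Read depth is unknown, since the lists hold no read counts. Intervals on shares of peaks or genes are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

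Peaks on chromosomes 1 to 19, X and Y were analysed; the peaks on other sequences, at most 12 per list, entered no comparison. Notes deposited beside the lists were not used. All peak ends lay within the lengths of the GRCm38 sequence, the assembly that mm10 names, and gene models were those of GENCODE mouse release 21. The annotation held 21938 protein-coding genes with 93513 transcript start sites. A promoter peak was a peak overlapping the window of 1 kb on either side of any annotated start site of a protein-coding gene. A distal peak lay more than 2.5 kb from every such site. Coordinates are 1-based.

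Overlap between lists required 1 bp. It was set beside 100 seeded circular shifts of the peaks along each chromosome, which keep peak widths and spacing. For each of 20 gene lists written before the data were examined, the share of genes with a replicated promoter peak was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists. Genes are not independent replicates, and neighbouring genes can share a peak, so these p-values describe this list of peaks and not a spread between animals. The strength of promoter peaks in the erythroid and fetal hepatocyte lists was compared by a two-sided permutation test of gene labels with 100000 resamples, on the percentile of each gene's strongest promoter peak among all replicated peaks. Words for 6 transcription factor motifs, and the GATA word read backwards as a control, were searched in distal peaks and in windows of the same width 5 kb to 1 side that overlapped no peak of any list. Pairs in which only 1 of both windows held the word were compared by an exact binomial test, adjusted over the 7 words. X-linked and autosomal genes were compared by Fisher's exact test.

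The genes named in the text follow a rule fixed together with the gene lists. It takes, for each list, up to 4 members with the strongest replicated promoter peak and the first 4 without one in alphabetical order. Any member of the erythroid, haem synthesis, embryonic globin and fetal hepatocyte lists may be named. The 10 strongest replicated peaks, the 10 longest domains (replicated peaks joined when at most 1 kb apart) and the albumin, beta-globin and alpha-globin neighbourhoods, each with 20 kb added on both sides, complete it. Outside this rule, the genes Mir144, Mir451a, Mir122, Hoxa4, Hoxb4, Cdk1, Tyms, Mcm7 and Mcm2 were chosen after their values were seen.

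The alternatives fixed beforehand were other overlap rules, a −log10 q of at least 2, the 20000 peaks of highest −log10 p, start-site windows of 500 bp and 2.5 kb, a distal distance of 5 kb, covered bases within 5 kb in place of the strongest peak, and each replicate's own list in place of the replicated list, which leaves out the other replicate. Others were added after seeing the data: 1 start site per gene, promoters split by CpG content, every motif read backwards, and motif pairs matched on GC content within 2 percentage points. A promoter was called CpG-rich when the 500 bp on either side of the gene's 5′ end had at least 50% GC and a CpG observed-over-expected ratio of at least 0.6.

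The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data. For the overlap between replicates, 60.0% of 3498 simulated peaks were found to overlap where 60% were planted. For the gene lists, 2 of 2 planted lists and 0 of 18 random lists were called among 2000 simulated genes. For the erythroid and fetal hepatocyte comparison, 4.0% of 200 simulated comparisons without a shift fell under 0.05. For the motifs, 1 of 7 words was called in 2000 simulated pairs, the planted one. Both windows of a simulated pair were random sequence with equal base frequencies. The simulation therefore did not cover a difference in GC content between peaks and flanks.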

Results

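H3K9ac was mapped in embryonic mouse liver at day 15.5, the stage at which the liver is a blood-forming organ and also holds immature hepatocytes. The 2 biological replicates formed a single group. On the 21 chromosomes analysed, the authors' list for replicate 1 held 46079 peaks covering 26.0 Mb and that for replicate 2 held 69893 peaks covering 34.7 Mb, so that replicate 2 had 1.52 times as many deposited peaks. The pooled list held 57677 peaks and the replicated list 26721. Replicated peaks were wider than those of the other lists, with a median width of 794 bp against 322 bp in the pooled list, 303 bp in replicate 1 and 252 bp in replicate 2. Coordinates are on mm10, and the signal of a peak is the authors' own value, used only within a list. The replicated peaks covered 29.2 Mb.

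The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 65.5% (95% confidence interval 65.1 to 65.9) overlapped a peak of replicate 2, whereas 39.7% (39.3 to 40.1) of the replicate 2 peaks overlapped a peak of replicate 1. After circular shifts the mean shares were 2.77% and 1.86%, and none of the 100 shifts exceeded 3.35% and 2.27%, respectively. The covered bases had a Jaccard index of 0.499, with 20.2 Mb shared. Across the 30186 shared peaks of replicate 1, the ranks of the signal in both lists were related with Spearman's rho of 0.736; this value is across peaks, which are not independent replicates. Peaks without a counterpart were narrow: their median width was 208 bp in replicate 1 and 203 bp in replicate 2, against 477 bp and 644 bp for shared peaks. The shares depended on the peaks taken, reaching 87.2% and 81.4% among the 20000 peaks of highest −log10 p in each list.

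Overlap rose with peak strength in both replicates. In the strongest quintile of replicate 1 peaks, all 9216 were found in replicate 2, and 99.2% of the 13979 strongest replicate 2 peaks were found in replicate 1. In the weakest quintile the shares were 30.4% and 10.1%. The classes in between rose in order, from 42.5% to 60.6% and 94.1% in replicate 1 and from 12.7% to 19.5% and 57.1% in replicate 2. At the level of genes the lists were closer than at the level of peaks: 11828 protein-coding genes had a promoter peak in replicate 1 and 13191 in replicate 2, and 11586 had one in both, which was 98.0% of the former and 87.8% of the latter.

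**Figure D1:**
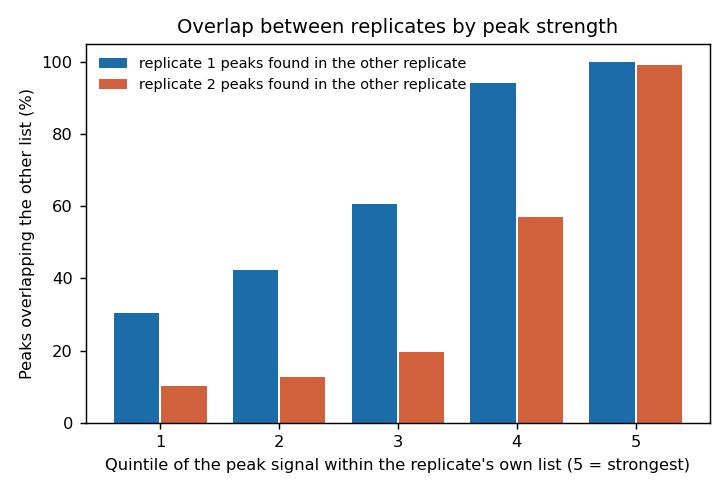
Share of peaks (%, vertical axis) of each replicate that overlap a peak of the other by at least 1 bp, for 5 classes of peak signal within the replicate's own list (horizontal axis, 5 is strongest). Bars rise from 30.4% to 100% for replicate 1 and from 10.1% to 99.2% for replicate 2.

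The replicated list was then compared with its sources. Every one of its 26727 deposited peaks was present unchanged in the pooled list, of which it kept 46.3% (45.9 to 46.7) on the chromosomes analysed. Of the kept peaks, 88.6% overlapped a peak in both replicates' own lists, 9.91% overlapped replicate 2 alone, 1.40% replicate 1 alone and 29 peaks overlapped neither. Of the 30956 dropped peaks, 316 overlapped both. When at least 50% of the pooled peak had to be covered, 73.5% of kept and 0 of the dropped peaks met the rule in both replicates. Kept peaks had a median signal of 4.63 and a median width of 794 bp, and dropped peaks 2.41 and 228 bp. The genomic descriptions that follow use the replicated list.

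Promoters of protein-coding genes held 15488 of the replicated peaks, 58.0% (57.4 to 58.6), against a mean of 5.79% and a maximum of 6.71% in 100 circular shifts. A further 3.82% lay at start sites of other annotated genes, 4.37% in exons, 19.8% in introns and 14.0% between genes. Promoter peaks were the strongest class, with a median signal of 8.53 (interquartile range 4.26 to 14.5) and a median width of 1143 bp. Intronic peaks had a median signal of 3.18 (2.80 to 3.90) and intergenic peaks 3.47 (2.92 to 4.51). Promoters made up 97.8% of the strongest quintile and 24.9% of the weakest quintile. The promoter share was 34.0% in replicate 2's own list and 43.9% in that of replicate 1, both of which contain more weak peaks.

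The peak of highest signal lay at the promoter of Sp3, a transcription factor of GC boxes, on chromosome 2 from 72977857 to 72981911, with a signal of 38.4. The next were at Ddx6, an RNA helicase (36.3), Ep300, a histone acetyltransferase (35.1), Ip6k1 (34.6), Dcun1d1 (33.8), Wtap, a component of the RNA methylation complex (33.6), and Top1, a DNA topoisomerase (33.3). Ubtf, a transcription factor of ribosomal DNA, followed at 32.6 and Sppl3 at 32.4. In 1 of the 10 strongest peaks the nearest protein-coding start site, that of Chd2, was 14.8 kb away; this peak, on chromosome 7 from 73556627 to 73558565, lay at the start site of an annotated gene that is not protein-coding.

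Among the 20 gene lists, 5 had replicated promoter peaks more often than other protein-coding genes, 10 less often, and 5 did not pass the threshold. All 28 erythroid genes, all 21 cell-cycle genes and all 20 housekeeping genes had one, against 53.2%, 53.3% and 53.3% of the respective other genes (Fisher's exact test, adjusted p = 7.96e-07, 1.93e-05 and 2.43e-05). Of the 12 genes for haem synthesis and its transport steps, 11 had a peak (exact test, adjusted p = 0.0127), the exception being Slc25a37, a mitochondrial iron importer. The fetal hepatocyte list had a peak at 24 of 32 annotated genes, a share with an interval from 56.6% to 88.5% (exact test, adjusted p = 0.0263). This last call was lost with a window of 500 bp, where the share was 65.6% (exact test, adjusted p = 0.200), and with 1 start site per gene (exact test, adjusted p = 0.202), and the call for haem synthesis was lost with replicate 2's own list (exact test, adjusted p = 0.0613). Genes are not independent replicates, so the tests describe these lists of peaks. The strongest cell-cycle promoters were Mki67, a marker of proliferating cells (30.2), Top2a (18.9), Mcm6, a helicase subunit of DNA replication (18.4), and Aurkb, a mitotic kinase (17.3), and the strongest housekeeping promoters were Ubc (25.7), Ywhaz (24.4), Rplp0 (22.8) and Actb (21.5). The 17 CpG-rich members of each of these lists all had a peak, but so did 85.3% of all CpG-rich promoters. This split, made after seeing the data, used the gene's 5′ end, whereas a peak at any start site counted. With it, 0 lists were called higher among CpG-rich promoters, with or without adjustment (Fisher's exact test). None could have been, as 17 of 17, the highest share possible in the largest lists, gave p = 0.159 (Fisher's exact test). Among CpG-poor promoters 4 lists were called higher: erythroid, haem synthesis, fetal hepatocyte and cell cycle (exact test, adjusted p = 3.12e-12, 0.000854, 7.57e-06 and 0.0299). The 4 cell-cycle genes of that class, Cdk1, Tyms, Mcm7 and Mcm2, lay near its limit of 0.6, with CpG ratios of 0.526, 0.544, 0.559 and 0.596.

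Peaks at the erythroid promoters ranged from 28.9 to 4.63 in signal and from 10477 bp to 215 bp in width. The strongest was at Sptb, the beta-spectrin of the red cell skeleton (chromosome 12, 76706427 to 76710138). Zfpm1, the cofactor of GATA1 known as FOG1, had a peak of 10477 bp with a signal of 26.6, and Lmo2 and Klf1, both erythroid transcriptional regulators, had signals of 24.2 and 21.8. Gata1 itself, on the X chromosome from 7965134 to 7967875, had a signal of 10.4. The lowest signals were at the adult globin genes Hba-a2 (8.22), Hba-a1 (7.77), Hbb-bt (5.49) and Hbb-bs (4.63) and at Spta1, the alpha-spectrin of the red cell (6.27). The Hba-a1 peak (32280116 to 32283049) ended before the gene's start at 32283511. The Hba-a2 peak (32293628 to 32295903) likewise ended before the start at 32296489. Whether reads from similar globin copies could be placed is not shown by the lists, so these values are not shown to be low acetylation. In haem synthesis the highest values were at Abcb10, a mitochondrial transporter (30.3), Fech, which inserts iron into protoporphyrin (22.9), Hmbs (22.1) and Urod (20.7), whereas Alas2, the erythroid enzyme of the first step, had 8.90. The Hmbs and Urod peaks also cover start sites of H2afx and Hectd3. Of the embryonic globin genes, Hbb-bh2 (3.27) and Hba-x (2.71) had a promoter peak and Hbb-y and Hbb-bh1 had none, and this list of 4 was not called different from other genes (exact test, adjusted p = 1.0). The list is too small to be called higher: 4 of 4, with windows of 2.5 kb, gave p = 0.130 (exact test).

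Fetal hepatocyte genes had weaker peaks. The median signal of the strongest promoter peak was 3.60 (interquartile range 3.16 to 4.33) over the 24 fetal hepatocyte genes with a peak and 15.5 (10 to 19.7) over the 28 erythroid genes. In percentiles of all replicated peaks the medians were 34.9 and 87.3, a difference of 52.4 (permutation test, two-sided, p = 1e-05, the smallest value that 100000 resamples can give). The highest value, 18.8 at Foxa3, belonged to a peak that also covers a start site of Sympk, and the next, 7.56 at Apoh, to a peak shared with Prkca. Cebpa, a transcription factor of hepatocytes, had 5.42, Prox1 5.12, Hnf1a 3.89 and Hnf4a 3.88. The secreted proteins Apoa1, Ttr and Apob had 4.25, 3.54 and 3.54. No replicated promoter peak was present at Alb, Afp, Ahsg, Fga, Fgb, Nr1h4, Onecut2 or Tbx3, although Alb and Ahsg had a promoter peak in each replicate's own list and in the pooled list, Fgb, Nr1h4, Onecut2 and Tbx3 in that of replicate 2 and Afp in that of replicate 1. With replicate 2's own list, 30 of 32 members had a peak (exact test, adjusted p = 0.000217). At Alb the peaks of both replicates did not overlap each other. H19, which is not protein-coding, had a peak at its start site with a signal of 3.17. With replicate 2's own list alone, the difference in median percentile was 22.1 (permutation test, p = 1e-05). The median percentiles there were 94.8 for erythroid and 72.7 for fetal hepatocyte genes, and the median signals 14.9 and 3.85. Percentiles depend on how many weak peaks a list holds, so the smaller difference is not shown to be a smaller contrast in signal.

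**Figure D2:**
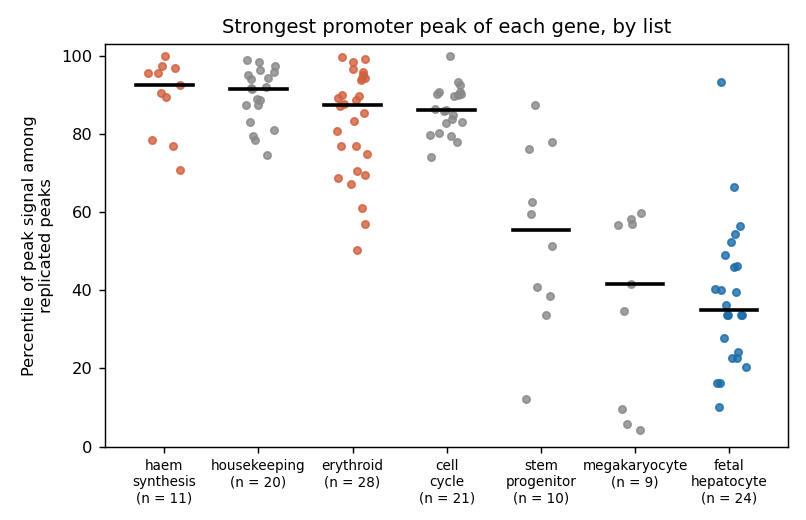
Percentile of the signal of each gene's strongest promoter peak among all replicated peaks (vertical axis) for 7 gene lists (horizontal axis, n is the number of genes with a peak). Points are genes and bars are medians, which were 87.3 for the erythroid and 34.9 for the fetal hepatocyte list.

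The mature hepatocyte list had a replicated promoter peak at 3 of 25 genes (exact test, adjusted p = 7.95e-05). These were Glul, glutamine synthetase (21.3), Gls2, a glutaminase (6.83), and Hpd, an enzyme of tyrosine breakdown (3.48). Arg1, Baat, Bhmt and Cps1 were the first members without one. Stem and progenitor genes had a peak in 10 of 17 cases (exact test, adjusted p = 0.899), led by the transcription factors Runx1 (15.5), Lyl1 (11.5, at a peak shared with Nfix), Myb (10.9) and Etv6 (6.58), while Cd34, Flt3, Gata2 and Hoxa9 had none. Megakaryocyte genes had one in 9 of 17 cases (exact test, adjusted p = 1.0), with Fli1 at 5.97, Gp9 at 5.69, Rab27b at 5.49 and Itga2b at 5.44. Macrophage genes had one in 5 of 17 (exact test, adjusted p = 0.0676), the strongest at Slc40a1, the iron exporter ferroportin (13.4), and cholangiocyte genes in 5 of 14 (exact test, adjusted p = 0.334), the strongest at Sox4 (7.07).

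Granulocyte and monocyte genes had a peak in 5 of 20 cases (exact test, adjusted p = 0.0185), a call that was lost with windows of 2.5 kb (exact test, adjusted p = 0.0549) and with 1 start site per gene (exact test, adjusted p = 0.0590). B-lymphoid genes had one in 2 of 15 cases and T-lymphoid genes in 3 of 16 (exact test, adjusted p = 0.00511 and 0.0149). The strongest lymphoid peak, at Vpreb1 (14.2), was shared with Top3b. Ebf1 had 3.05, and Cd19 and Cd79a had none. Endothelial genes had a peak in 3 of 18 cases, at Egfl7 (6.46), Eng (4.50) and Kdr (2.68), and stellate and mesenchymal genes in 2 of 17, at Reln, an extracellular matrix protein (19) and Pdgfrb (3.25), with exact-test adjusted p = 0.00358 and 0.00184. Of the lists for organs other than liver, neuron genes had 1 of 19 (Syp, 2.22), muscle genes 2 of 19 and other organs 2 of 17, with exact-test adjusted p = 7.24e-05, 0.000685 and 0.00184. The higher of both muscle values, 22.8 at Mylpf, belonged to a peak shared with Tbc1d10b. None of the 16 posterior Hox genes had a peak (exact test, adjusted p = 2.53e-05). With replicate 2's own list, 6 lists in place of 10 were lower than other genes, the calls for granulocyte and monocyte, endothelial, stellate and mesenchymal, and muscle genes being lost; with replicate 1's own list 8 were lower, without those for granulocyte and monocyte and B-lymphoid genes. With replicate 2's own list the counts were 6 of 25 for mature hepatocyte, 5 of 16 for T-lymphoid, 4 of 19 for neuron, 4 of 17 for other organ and 2 of 16 for posterior Hox genes, and with replicate 1's own list they were 5, 3, 1, 2 and 1, all lower than other genes by the exact test. Among CpG-rich promoters 4 lists were lower than other genes, and among CpG-poor ones 1 was.

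**Figure D3:**
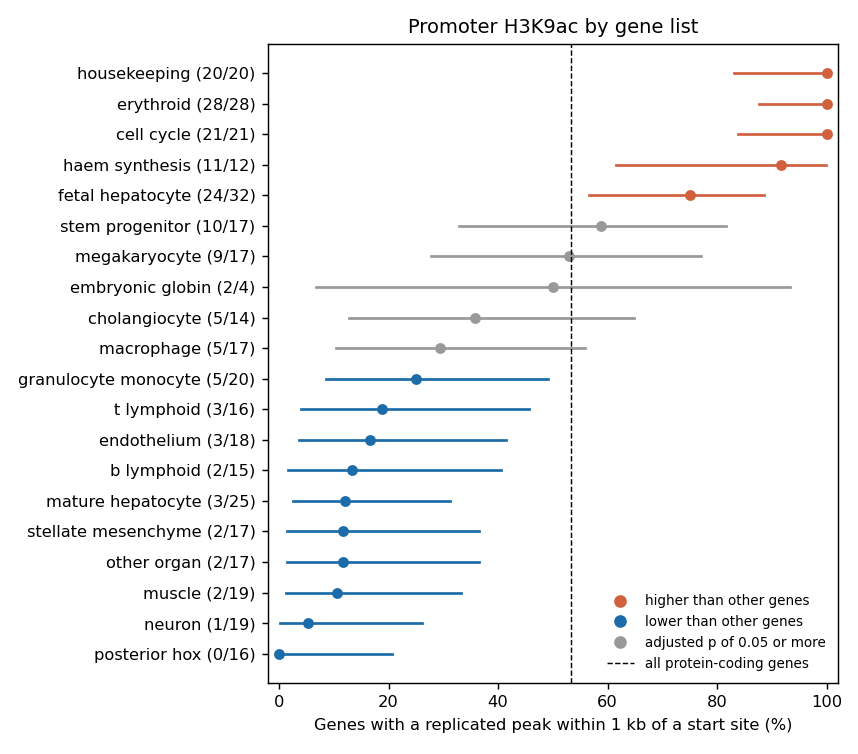
Share of genes (%, horizontal axis) with a replicated peak within 1 kb of a start site, for 20 gene lists (vertical axis, with counts). Lines are exact 95% binomial intervals, the dashed line marks all protein-coding genes (53.3%), and colour marks lists higher (5) or lower (10) than other genes at an adjusted p under 0.05.

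Joining replicated peaks at most 1 kb apart gave 17229 domains with a median length of 1426 bp. The longest, 51.7 kb with 16 peaks, spanned the start sites of Zfpm1 on chromosome 8 from 122280594 to 122332278. The next, 35.3 kb, held the start sites of Ank1, the ankyrin of the red cell membrane. They were followed by domains at Stradb and Trak2 (25.4 kb), Rbm38, an RNA-binding protein (24.4 kb), Nprl3, whose introns hold the alpha-globin enhancers (22.6 kb), and the adult alpha-globin genes with Hbq1a and Hbq1b (22.1 kb). The remaining 4 of the 10 longest lay at Epb41, the red cell protein 4.1, together with Gm10300 (21.6 kb), Tmcc2 (20.8 kb), Hemgn, an erythroid nuclear protein (18.9 kb), and Cd82 (18 kb). In each replicate's own list the Zfpm1 domain was covered to 74.8% and 89.4%.

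The globin and albumin neighbourhoods differed in their number of replicated peaks. The alpha-globin neighbourhood (chromosome 11, 32205628 to 32320873) held 48 replicated peaks covering 56.0 kb, the strongest with a signal of 21.6. That peak, from 32266670 to 32270924, covers the 5′ end of Nprl3 and no globin gene. The neighbourhood takes in the whole Nprl3 gene, so its count is not of globin genes alone. The strongest promoter peaks of Hba-a1 and Hba-a2 had signals of 7.77 and 8.22. The beta-globin neighbourhood (chromosome 7, 103792524 to 103873216) held 30, covering 18.3 kb, the strongest with 8.94. That peak, from 103870078 to 103870966, lies beyond Hbb-y, the last of the globin genes drawn, which ends at 103853216. Other replicated peaks also lie beyond Hbb-y, so this count is not of globin genes alone either. The neighbourhood of Alb and Afp (chromosome 5, 90440897 to 90528907), which encode the main serum proteins of adult and fetal liver, held none. It held 3 pooled peaks, with −log10 q values of at most 1.83, and 2 peaks in each replicate's own list.

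**Figure D4:**
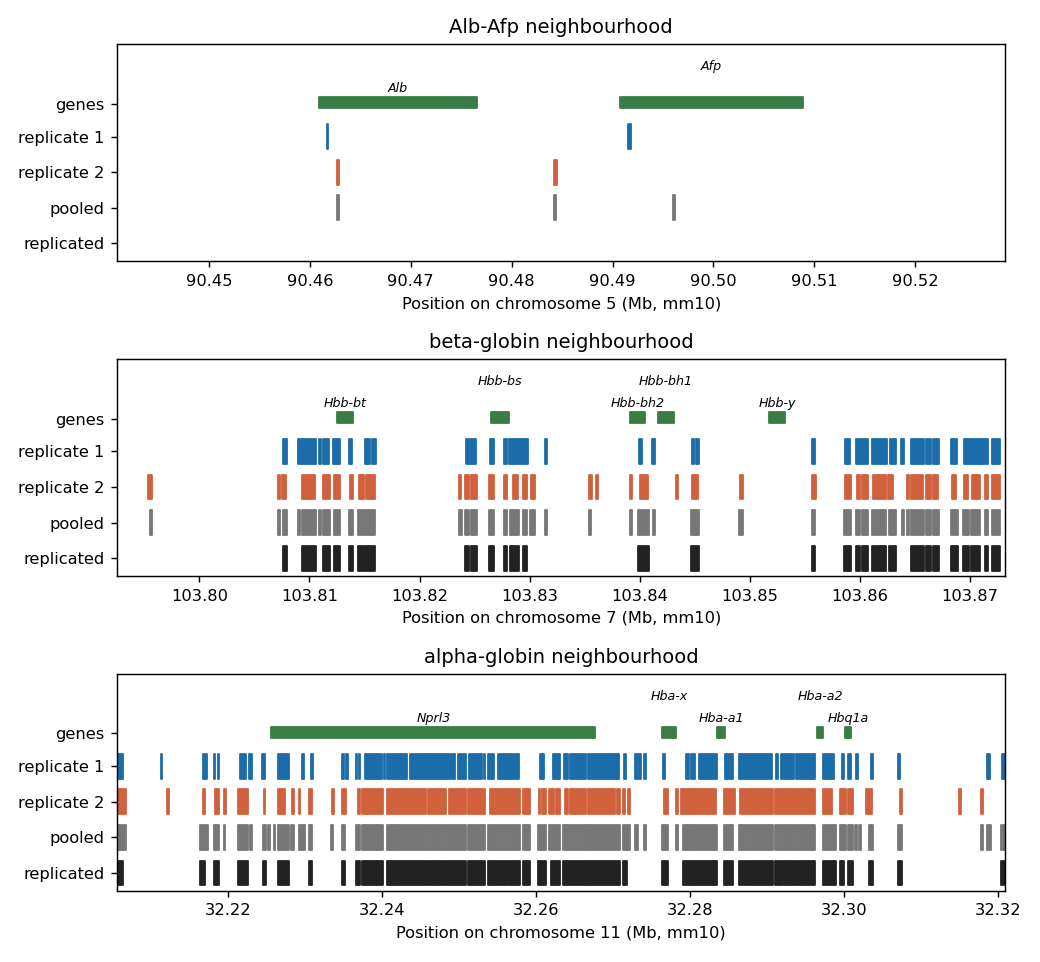
Peaks of each list (a line of bars for each) along the Alb-Afp, beta-globin and alpha-globin neighbourhoods (horizontal axes, position in Mb on mm10), with gene bodies in green. The replicated list has 0, 30 and 48 peaks in them.

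The motif comparison covered 8828 distal replicated peaks, 33.0% of the list, of which 7483 had a flanking window free of peaks. Distance was taken to start sites of protein-coding genes only, so peaks at start sites of other annotated genes can be among them. The KLF word was present in 28% of peaks and 19.1% of flanks (exact binomial test, adjusted p = 9.22e-43), the AP-1 word in 12.5% and 10.5% (exact test, adjusted p = 0.000163) and the CTCF word in 0.762% and 0.321% (exact test, adjusted p = 0.000444). The CEBP word was less frequent in peaks, 15.3% against 17.5% (exact test, adjusted p = 0.000266), with a ratio of 0.838 (0.765 to 0.919), and the same word read backwards had a ratio of 0.682 (0.622 to 0.748). The GATA word was present in 59.8% of peaks and 61.0% of flanks (exact test, adjusted p = 0.114), and the HNF4 word in 1.82% and 1.91% (exact test, adjusted p = 0.719). The control word, GATA read backwards, was present in 46.3% of peaks and 54.3% of flanks (exact test, adjusted p = 1.32e-24). Peaks had a mean GC content of 50% and flanks of 45.2%. Among the 1543 pairs matched on GC content, chosen after seeing the data, 0 of the 7 words passed the threshold after adjustment, with GATA (63.7% against 59.5%) and AP-1 (14.3% against 11.7%) under 0.05 before it, and the KLF and CEBP differences turned, to -0.518 and 1.49 percentage points. With replicate 1's own list the CTCF call was lost, with a difference of 0.059 points. With replicate 2's own list GATA was lower in peaks by the test, at -3.17 points, and the control word was at -5.96 points. The KLF difference of 8.97 points was 1.93 points with replicate 1's own list and 3.04 with that of replicate 2. The AP-1 difference of 2.03 points was then 0.574 and 0.679, and the CEBP difference of -2.20 points was -0.831 and -1.56. Median peak widths over all peaks were 303 bp and 252 bp in those lists, against 794 bp in the replicated list. The windows searched thus differed in width, so these differences in points are not directly comparable between lists.

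**Figure D5:**
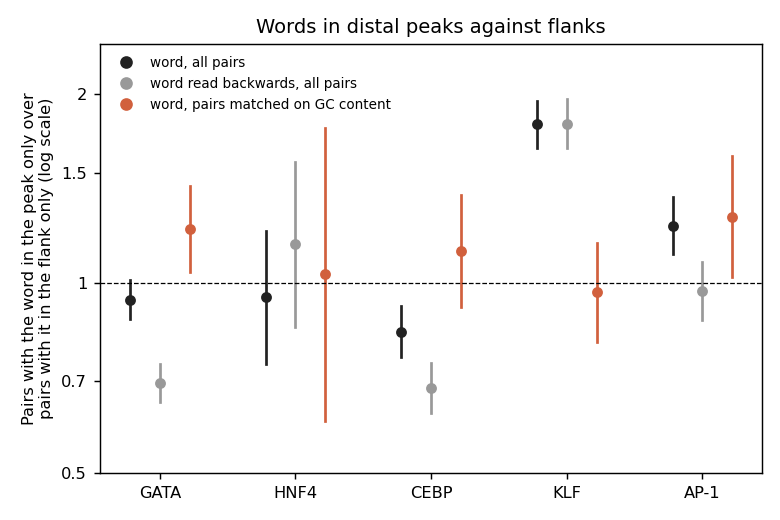
Ratio of pairs with a word in the distal peak alone to pairs with it in the flank alone (vertical axis, log scale, lines are exact 95% intervals) for 5 motif words (horizontal axis). KLF has 1.79 both forwards and backwards, and GATA has 0.942 forwards, 0.695 backwards and 1.22 in pairs matched on GC content; the backward KLF word can hold the same CACCC core, and CTCF is left out because its backward word occurred in only 1 pair of each kind.

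On the X chromosome, 313 of 948 protein-coding genes had a replicated promoter peak, 33.0%, against 11379 of 20807 autosomal genes, 54.7% (Fisher's exact test, two-sided, p = 2.09e-39). The median signal of these peaks was 7.72 on X and 12.4 on autosomes. Both pools were of mixed sex, and no correction for the number of X copies was made. The X values therefore do not measure acetylation per copy. Among CpG-rich promoters, a split made after seeing the data, the shares were 72.1% and 85.6% (exact test, p = 2.98e-07). The density of replicated peaks was highest on chromosome 11, with 19.8 per Mb, and it was 3.22 per Mb on X. The Y chromosome held 3 replicated peaks.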

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

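The tests of peak strength in other cell types, of dropped peaks, of the AP-1 word read backwards, of promoters split by CpG content and of pairs matched on GC content were chosen after the main results were seen.

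Signal was present outside the chromosomes analysed. On unplaced or mitochondrial sequence lay 12 peaks of the replicate 1 list, 6 of the replicate 2 list, 8 of the pooled list and 6 of the replicated list. They were picked out because no comparison used them. The strongest in the replicated list, on an unplaced sequence of chromosome 4, had a signal of 15.7.

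The gene lists differed in how often their promoters carried a peak, and promoters rich in CpG carried one more often in general, 85.3% of 9738 against 27.8% of 12200. CpG content alone did not account for the erythroid and neuron lists. All 23 erythroid genes with a CpG-poor promoter, whose CpG ratios were at most 0.490, had a peak, 72.3 percentage points above other genes of that class, and 0 of 10 neuron genes with a CpG-rich promoter had one, 85.3 points below (Fisher's exact test, adjusted p = 3.12e-12 and 4.02e-08). The class was that of the gene's 5′ end, whereas a peak at any annotated start site counted, so some peaks may lie at another start site. With 1 start site per gene, the 5′ end, 26 of the 28 erythroid genes had a peak. CpG content stays open for the cell-cycle and housekeeping lists, each with 17 of 17 CpG-rich promoters against 85.2% (exact test, adjusted p = 0.387): the 4 of 4 CpG-poor cell-cycle promoters (exact test, adjusted p = 0.0299) had CpG ratios of 0.526 to 0.596, just under the limit, and housekeeping had 3 of 3 (exact test, adjusted p = 0.0717). The test among CpG-rich promoters cannot decide this, since 17 of 17 is the highest share possible and did not pass. CpG content also stays open for the granulocyte and monocyte, B-lymphoid, T-lymphoid, muscle and other organ lists, called lower among all genes. Their CpG-poor members had a peak in 11.8%, 7.14%, 14.3%, 5.88% and 11.8% of cases, against 27.8% of other genes of that class. These shares were lower but not called (exact test, adjusted p = 0.327, 0.292, 0.441, 0.156 and 0.327). No biological explanation was tested, since the design has 1 group.

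Alb and Afp, genes that define hepatocytes, lacked a replicated promoter peak, and the fetal hepatocyte promoters with a peak were weaker than the erythroid ones. The tables argue against low CpG content as the whole cause of the weakness, since the difference in median percentile was 49.6 among CpG-poor promoters alone (permutation test, p = 2e-05). Here too the class was that of the 5′ end, whereas the strongest peak at any start site was taken. For the missing peaks, the step from the pooled to the replicated list may be part of the reason. Of the 8 genes without a replicated peak, 5 had a pooled one, with signals of 2.19 to 3.41, and only Fga had none in any list. The same share among other genes without a replicated peak is not given here. The count of 5 of 8 therefore cannot show whether this is particular to fetal hepatocyte genes. A mixed tissue in which cells other than erythroid ones are the minority is a candidate explanation for the weakness: the 47 genes with a peak in the 10 other lists of liver or blood cell types also had weaker peaks, with a median −42.8 percentile points from the erythroid one (permutation test, p = 1e-05, the smallest value the resamples can give). The list medians were known when that test was chosen, it does not separate few cells from low acetylation per cell, and no biological explanation was tested.

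Words in distal peaks were compared with flanks that had less GC. The KLF excess goes with base composition, because the ratio was 1.79 (1.64 to 1.95) in all pairs and 0.968 (0.807 to 1.16) in GC-matched pairs; the backward word, which can hold the same CACCC core, is no control here. With the backward word as control, the AP-1 excess is not accounted for by base composition, as that word had a ratio of 0.973 (95% interval 0.874 to 1.08) against 1.24 (1.11 to 1.37) forwards. In GC-matched pairs the AP-1 ratio was 1.28 (1.02 to 1.59). After adjustment over 7 words it did not pass the threshold there (exact test, adjusted p = 0.102). For GATA, base composition may have hidden an excess, as for CEBP (0.838 forwards, 0.682 backwards, 1.13 in GC-matched pairs with an interval of 0.918 to 1.38), where this stays open; the GATA ratio was 0.942 (0.877 to 1.01) forwards and 0.695 (0.648 to 0.745) backwards, and in GC-matched pairs the ratio was 1.22 (1.04 to 1.43), although after adjustment over 7 words it did not pass the threshold (exact test, adjusted p = 0.0864). Only 1543 of 7483 pairs could be matched, and no biological explanation was tested.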

How the results depend on the processing

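The settings with 1 start site per gene, CpG-rich or CpG-poor promoters, words read backwards and GC-matched pairs were chosen after seeing the data. Of the alternatives chosen beforehand, 127 kept their direction and side of the threshold, their interval or, for counts, stayed within 1.5 times, 19 values moved, 10 calls were lost, 3 were gained and 7 turned direction; of the added ones 34 held, 4 moved, 20 calls were lost and 17 turned. All 7 of the former, and 10 of the latter, were results not called under either setting: megakaryocyte (52.9% with 500 bp, 58.8% with 2.5 kb, 52.9% to 64.7% when a replicate was left out, 100% and 50% of CpG-rich and CpG-poor promoters), embryonic globin (100% with 2.5 kb, 50% to 75% when a replicate was left out, 50% with 1 start site and among CpG-poor promoters), stem and progenitor (47.1% with 1 start site, 75% of CpG-rich promoters), macrophage and cholangiocyte (29.4% and 30% of CpG-poor promoters), GATA in GC-matched pairs (4.21 points) and HNF4 (0.0648 points in GC-matched pairs, 0.0137 with a −log10 q of at least 2, -0.0849 to 0.0697 when a replicate was left out). The cause was not tested except where the construction shows it. The share of replicate 1 peaks found in replicate 2 was 59.5% with at least 50% of the peak covered, 40.6% with 50% both ways, 79.0% with a −log10 q of at least 2 and 87.2% among the 20000 of highest −log10 p, and that of replicate 2 peaks was 33.2%, 26.8%, 51.9% and 81.4%. With at least 50% of the peak covered, the weakest and strongest quintiles had 22.5% and 99.9% in replicate 1 and 6.45% and 95.8% in replicate 2, and 73.5% of kept peaks were in both lists. The promoter share was 54.0% with windows of 500 bp, 67.0% with 2.5 kb, 47.4% with 1 start site per gene, 37.1% in the pooled list, and 34.0% to 43.9% when a replicate was left out; wider windows take in more peaks by construction. Leaving out a replicate gave 6 to 8 lower lists, and the shares were 30% to 35.0% for granulocyte and monocyte, 91.7% in both for haem synthesis, 16.7% to 38.9% for endothelial, 17.6% to 41.2% for stellate, 10.5% to 36.8% for muscle and 20.0% to 33.3% for B-lymphoid genes. Calls were lost for fetal hepatocyte genes with 500 bp (65.6%) and 1 start site (62.5%), and for granulocyte and monocyte genes with 2.5 kb (30%) and 1 start site (25%). Among CpG-rich promoters 0 lists were higher and 4 lower; haem synthesis (80.0%) and fetal hepatocyte (71.4%) turned to below other genes, mature hepatocyte, granulocyte and monocyte, and B-lymphoid (each 100%, with at most 3 genes) to above, and calls were lost for erythroid, cell cycle and housekeeping (each 100%) and for T-lymphoid and muscle (each 50%). No list could be called higher in this class, since a share of 100% did not pass even in the largest lists. Among CpG-poor promoters 4 lists were higher and 1 was lower. Calls were lost there for granulocyte and monocyte and other organs (11.8% each), B-lymphoid (7.14%), T-lymphoid and endothelial (14.3% each) and stellate genes (9.09%). They were also lost for neuron (11.1%), muscle (5.88%), posterior Hox (0%) and housekeeping genes (100%). Other organs kept all 17 genes in this class, whereas the rest of these lists had fewer. For other organs the share of other genes was 27.8% in this class and 53.3% among all genes. In GC-matched pairs, CEBP (1.49 points) and KLF (-0.518) turned, and AP-1 (2.66), CTCF (0.518) and GATA read backwards (-0.583) lost their calls, in fewer pairs. GATA was lower in peaks by the test over 5 kb from a start site (-1.86 points) and with a −log10 q of at least 2 (-1.82). When a replicate was left out, GATA was at -3.17 to -0.842 and CTCF at 0.059 to 0.0906. GATA read backwards was lower still in each of these settings, at -8.72, -8.07 and, with a replicate left out, -5.96 to -4.63. The GATA calls therefore do not separate the word from base composition. The erythroid minus fetal hepatocyte difference was 22.1 to 37.5 percentiles when a replicate was left out and the X minus autosome difference -25.2 to -22.5 points, all past the threshold. Leaving out a replicate also changes the list to that of the other replicate, with its weaker peaks. No paired analysis was possible because there is a single group. Read depth is unknown, so a missing peak was not called at this depth and is not shown to be absent.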

Other observations

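The crossing of lists with long domains and the gene families below were chosen after the results were seen. Domains of at least 10 kb numbered 92, and they held start sites of 10 of 28 erythroid genes and 4 of 12 haem synthesis genes, against 0.507% and 0.534% of other genes (Fisher's exact test, adjusted p = 4.3e-15 and 4.21e-06 over 20 lists). These genes were Ank1, Gypa, Hba-a1, Hba-a2, Hemgn, Lmo2, Nfe2, Slc4a1, Tal1 and Zfpm1, and Alad, Cpox, Fech and Hmbs. None of the 41 cell-cycle and housekeeping genes lay in such a domain, although the median percentiles of their promoter peaks were 86.2 and 91.6, beside 87.3 and 92.4 for erythroid and haem synthesis genes, and the difference from the 14 of 40 erythroid and haem genes passed an exact test (p = 1.27e-05). The strongest promoter peak had a median width of 3798 bp for erythroid and 5243 bp for haem synthesis genes, 2763 bp for cell-cycle and 2596 bp for housekeeping genes. Among the microRNA genes of both cell types, the erythroid Mir144 and Mir451a lay at a peak with a signal of 16.6, and Mir122, the main microRNA of hepatocytes, had no replicated peak at its annotated start. The annotated Mir122 gene spans only 65248861 to 65248926 on chromosome 18. Whether transcription starts there was not examined, so its promoter may lie elsewhere.

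Of 16 gene families named by their symbols, without members whose symbol marks a pseudogene, 15 passed Fisher's exact test against other genes after adjustment, and GATA factors, with a peak at 4 of 6, did not (exact test, adjusted p = 0.692). All 78 genes for mitochondrial ribosomal proteins and all 17 for cytosolic aminoacyl tRNA synthetases had a replicated promoter peak, as did 37 of 39 for proteasome subunits and 60 of 67 for clustered histone genes. All 18 autophagy genes named Atg and 80 of 84 cytosolic ribosomal protein genes had one. Of 394 zinc-finger protein genes named Zfp, 313 had one, 79.4%. By contrast, 1 of 1094 olfactory receptor genes, 1 of 327 vomeronasal receptor genes, 4 of 53 keratin genes and 3 of 49 genes of the cytochrome P450 family 2 had a peak. Near-identical copies in these large families can keep reads from being placed, which the lists do not show. Across the Hox clusters, Hoxa4 (3.41) and Hoxb4 (3.78) were the only genes with a peak, and the 9 Hoxc and 9 Hoxd genes had none.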
